A study of Mus musculus with 2 samples.

How the data were processed

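DNA immunoprecipitated with a Ring1B antibody (Cy5) and input DNA (Cy3) from mouse ES cells were hybridised together to 2 Agilent promoter tiling arrays, per the labels. Both arrays had the same dye orientation, and there was no dye swap and no mock immunoprecipitation. The source names of the labels begin with Muscle, whereas the titles name ES cells, and the titles were followed. The array files gave different array designs, 014716 for slide 1 and 014717 for slide 2, with no probe in common. The labels' numbering of the arrays was therefore read as slides and not as replicates.

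The deposited array files were made with Agilent Feature Extraction 9.1.3.1, per the file headers. The processed signals are fluorescence intensity values after background subtraction and 1 linear dye factor per channel, per the file headers, with very dim spots set to a surrogate (floor) value. The log ratio is the log10 of red over green processed signal, per the file headers. It was 0 for every spot with surrogates in both channels. The p-value per spot comes from the error model of that software, per the file headers, and was not used for calls. The deposited series table holds the log2 of the ratio of mean signals, without background subtraction or centring, as checked against the array files (largest difference 5.0e-05). Its column medians over all spots were 0.774 for slide 1 and 0.798 for slide 2, and one row number stands for different probes in its columns.

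The main value was the log2 ratio of the processed signals, red over green. Control spots and 141 and 17 probes marked as outliers on slides 1 and 2 were left out. Each slide was centred on its median probe, which stood at 0.23 on slide 1 and 0.16 on slide 2. The SD over probes was 1.33 and 1.44. Surrogates filled both channels at 18.2% of the probes of slide 1 and 15.5% of those of slide 2. Saturated immunoprecipitation signal was found at 31 and 58 probes.

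Probes were assigned to genes by the annotation in the array files, and older symbols were turned into present ones with a reference table of gene names. The array names numbered 17128, of which 12574 matched a symbol, 1980 an accession and 2107 an older symbol, and 467 matched none. A gene needed at least 3 probes. The median gene had 28 probes over 7542 bp, with a median spacing of 182.5 bp. Distances to the transcription start were given in the file of slide 1 only. For slide 2 the start was set at the boundary between probes annotated as promoter and as inside the gene. On slide 1 that boundary lay a median of 51 bp from the given start over 7816 genes. The genome build was not given in the sources used here, so coordinates were not lifted to another build.

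The design called for a limma test across arrays and, if the arrays carried different probes, for values of one array and genes named by size alone. The latter applied. The threshold was a mean log2 ratio of 1, and counts with the sign turned served as the yardstick. Each of 13 gene lists was compared with 10000 random lists of the same size, matched on slide, on 5 classes of input signal and on 5 of probe GC. The median's percentile among them was reported, and a list was taken to differ outside the middle 95%. Regions were runs of at least 3 probes whose running mean (probes within 500 bp on either side, at least 3) was at least 1, with gaps under 1000 bp.

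Genes were named by a fixed rule. It took the 15 highest and 5 lowest genes by mean, with 1 gene per shared promoter, and the 4 members of each list with the largest size. It also took 13 genes fixed by name, the 5 longest regions and the 5 regions with the highest mean. One gene of the Polycomb list that the rule takes is not reported here. The gene lists, this rule, the main settings and the first set of alternatives were chosen before the data were examined. The alternatives were normexp background correction (offset 50), loess within array, no centring, the deposited series table after centring, leaving out dim probes, GC-corrected ratios, the median of the probes and the best run of probes. Further ones changed the window around the start, the minimum number of probes, the threshold, and the window, gap and minimum run of the regions. After the data were seen, 3 were added: leaving out probes with surrogates in both channels, a minimum of 20 probes, and random lists matched on probe number too.

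The procedure was tested on simulated data made from random noise of each slide's SD, partly shared between neighbouring probes, on the real probe positions of 16882 genes, with 200 genes shifted. A shift of 1.5 was recovered at or above 1 for 98.0% of genes (median 1.55), and one of 2.5 for 100% (median 2.42). Unshifted genes passed in 0.402% of cases above and 0.439% below. Of 100 lists without shifted genes, 7.0% fell outside the middle 95%. Regions of at least 2000 bp covered 79.0% of the shifted genes, and 47 others lay above and 57 below. The data held more on the low side, with 1.87% of all genes at or below -1 and 172 such regions below. The simulation had no floor values and no GC trend, and its lists were drawn at random and not from gene clusters. It therefore does not give the error rate of the real lists.

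Computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.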

Results

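Ring1B, a Polycomb group protein encoded by Rnf2, was mapped at promoters of mouse embryonic stem (ES) cells by ChIP-chip. In this assay, chromatin is immunoprecipitated with an antibody and the recovered DNA is hybridised to a tiling array together with input DNA, the chromatin taken without the antibody. DNA from the Ring1B immunoprecipitation was labelled with Cy5 and input DNA with Cy3. The 2 arrays were the 2 slides of one promoter set and shared no probe. Slide 1 carried chromosomes 1 to 8 and part of 9, and slide 2 carried the rest. Each promoter was therefore measured once, and there were no replicates, no test and no p-value across genes. Slide 1 gave 237054 usable probes and slide 2 gave 237168. Input signal stood well above background at 74.1% of the probes of slide 1 and 76.3% of those of slide 2. For immunoprecipitated DNA the shares were 77.2% and 80.6%. The number of arrays limits the precision of every value. All values are log2 ratios of immunoprecipitated over input DNA, centred on the median probe of the slide. A gene's value is the mean over its promoter probes, given with the SD over those probes. The genome build of the coordinates is not given in the sources used here.

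The comparison of immunoprecipitated with input DNA asked which promoters carried Ring1B in ES cells. Promoters of developmental regulators had the highest ratios. Of 282 measured genes in 4 lists of developmental regulators, 149 had a mean log2 ratio of at least 1, 2-fold above the median probe, and 0 had one of -1 or less. The Hox genes, which set position along the body axis, led with a median of 1.41 and 27 of 33 genes at or above 1. Pluripotency genes, keratins and ribosomal protein genes had 0 members at or above 1 among 39, 71 and 80 measured. Of all genes, 2.00% were at or above 1, so 0 members in lists of this size says little. The keratin, ribosomal protein, olfactory receptor, histone and protocadherin lists had been fixed as groups not known as Polycomb targets in ES cells. Of these, olfactory receptors had 1 of 862 at or above 1, histone genes 6 of 66 and protocadherins 9 of 53. Histone genes and protocadherins lay at percentile 100 of their random lists.

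Most of the 15 highest genes encode homeobox proteins, transcription factors that pattern the embryo. Six3, a regulator of forebrain and eye development, had a log2 ratio of 2.39 ± 0.98 (SD, 25 probes; chromosome 17, 83916417 to 83921722), 5.23-fold above the median probe. Its divergent partner Six3os1 stood at 2.23. Meis2, a homeobox cofactor of Hox proteins that the array names Mrg1, had 2.31 ± 0.86 (36 probes; chromosome 2, 115803616 to 115811487). Olig2, which specifies oligodendrocytes and motor neurons, had 2.10 ± 1.13 (43 probes; chromosome 16, 91270187 to 91277974). Pitx1, a hindlimb regulator, and Pou3f2, a neural POU factor, both had 2.04. Otx2, needed for the anterior head, had 2.02 ± 0.92 (42 probes). Lef1, a nuclear effector of Wnt signalling, had 2.02 ± 1.29 (37 probes). The others were Hoxb3 at 2.15, Hoxa11 at 2.13, Hoxb6 at 2.04, Hoxc9 at 2.02, Hoxd10 at 2.01 and Nkx2-3 at 1.97, together with 2 uncharacterised transcripts. D930049A15Rik had the highest value of all, 2.52 ± 1.20 (15 probes; chromosome 14, 23130623 to 23132939), and D230002A01Rik had 2.14 (10 probes).

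In all 4 Hox clusters most measured genes were at or above 1. In HoxC on chromosome 15, 8 of 8 measured genes were at or above 1, and in HoxB on chromosome 11, 6 of 7. HoxA on chromosome 6 had 8 of 10 and HoxD on chromosome 2 had 5 of 8. The exceptions included Hoxa3 at -0.48, the lowest Hox gene, Hoxd4 at 0.31 and Hoxd1 at 0.34, chosen after their values were seen. The list's median of 1.41 lay at percentile 100 of 10000 random lists matched on slide, input signal and probe GC.

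The other developmental lists followed in order. Homeobox regulators outside the Hox clusters had a median of 1.23, with 60 of 96 genes at or above 1. Developmental transcription factors of other families had a median of 1.09, with 50 of 90 at or above 1. Examples of the latter were Zic1 at 1.94, Tfap2a at 1.94 and Gata6, a regulator of endoderm, at 1.93 ± 1.21 (42 probes; chromosome 18, 11253676 to 11261692). Gata4, another endoderm factor, had 1.47 ± 1.32 (42 probes), and Eomes, which acts in trophoblast and mesendoderm, had 1.12 ± 1.68 (39 probes). Cdx2, the trophectoderm regulator, had 1.02 ± 1.90 (43 probes), and Hoxc13 had 1.06. Signalling genes were lower, with a median of 0.48 and 12 of 63 at or above 1. Their highest members were Cyp26a1, which breaks down retinoic acid, at 1.61, the Notch ligand Dll4 at 1.54, and the growth factors Igf2 at 1.53 and Fgf9 at 1.52. All these lists lay at percentile 100 of their random lists, and none had a member at or below -1.

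**Figure D1:**
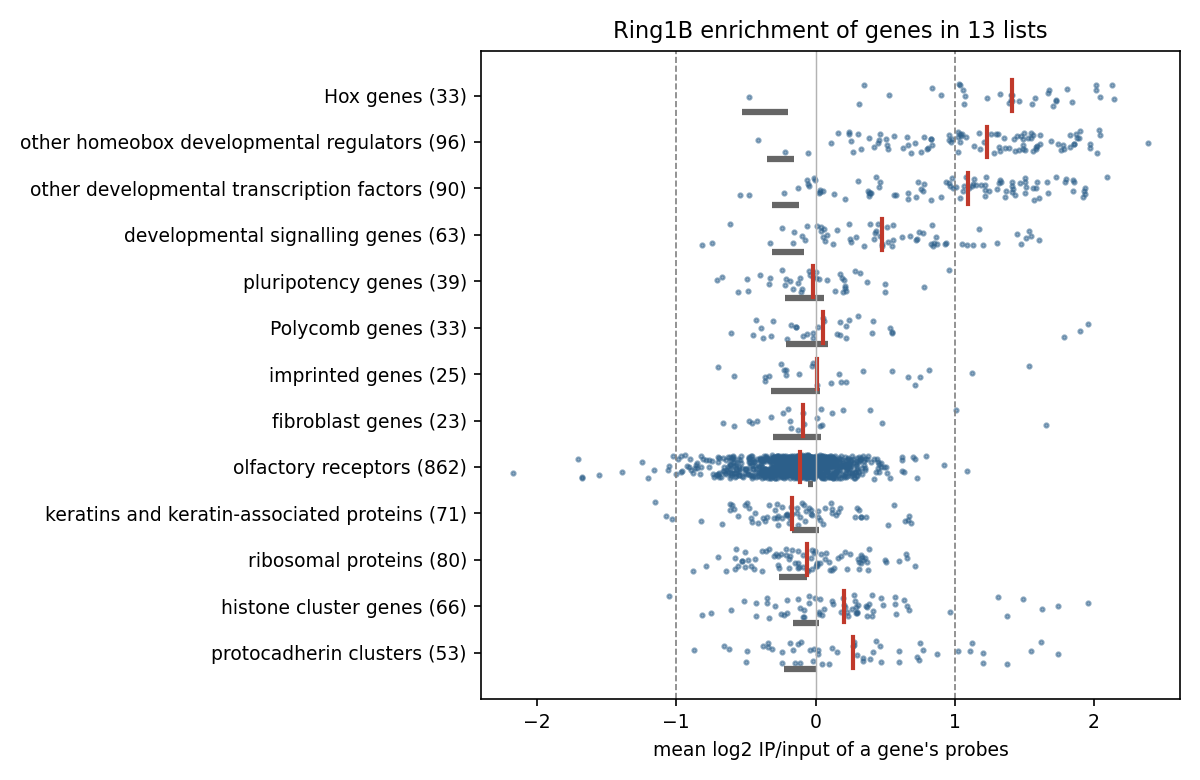
Mean log2 ratio of immunoprecipitated over input DNA for each measured gene (points) in the 13 lists, with the list median (red), the middle 95% of medians of matched random lists (grey bars) and the thresholds of 1 and -1 (dashed). Hox genes have a median of 1.41 and other homeobox regulators one of 1.23, and pluripotency genes have one of -0.02.

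Genes that keep ES cells pluripotent had a median of -0.02, at percentile 82.7, with 0 of 39 at or above 1 and 0 at or below -1. Pou5f1, which encodes Oct4, had -0.21 ± 1.47 (36 probes) and Sox2 had 0.32 ± 1.25 (38 probes). Gbx2, also a homeobox regulator, was the highest of the list at 0.96, and Tdgf1 had 0.78. Both carried a long region with a running mean of at least 1, of 3076 bp (mean 1.78) at Gbx2 and 3045 bp (mean 1.35) at Tdgf1, the only 2 of the list with one of at least 2000 bp. Gbx2 also had 873 bp with the sign turned (mean -1.53). Dppa5a had -0.67. The list's symbol Tcf3 was matched to the present gene of that name, the bHLH factor E2A (Tcfe2a on the array), which had -0.71. The factor called Tcf3 in work on pluripotency is now Tcf7l1, which had -0.07 and was chosen after its value was seen. Nanog and T were not analysed here, so 11 of 13 genes fixed by name were measured. The fibroblast list, fixed because cultures can hold feeder cells, had a median of -0.09, at percentile 66.8. Its members Pdgfra and Twist1, both also known in embryonic mesoderm, had 1.66 and 1.01, against -0.66 for Ogn and -0.59 for S100a4.

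Promoters of some Polycomb genes themselves were among the high ones. Of 33 Polycomb genes, 3 were at or above 1, and the list median was 0.06, at percentile 94.5. The percentile was 98.1, outside the middle 95%, with the deposited series table and 78.5 with GC-corrected ratios. Cbx8 had 1.79 ± 1.15 (42 probes; chromosome 11, 119147522 to 119154983), and Bmi1 had 1.90 ± 1.13 over only 12 probes. Cbx2, near Cbx8, had a mean of -0.02 ± 1.94 (39 probes; chromosome 11, 119126663 to 119134458). Its probes went both ways, with 1152 bp at a mean of 2.06 and another 1466 bp at a mean of -2.00. Rnf2, which encodes Ring1B, had -0.06 ± 1.07 (27 probes), its paralogue Ring1 had -0.14 ± 1.22 (15 probes), and Scmh1 had -0.61.

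**Figure D2:**
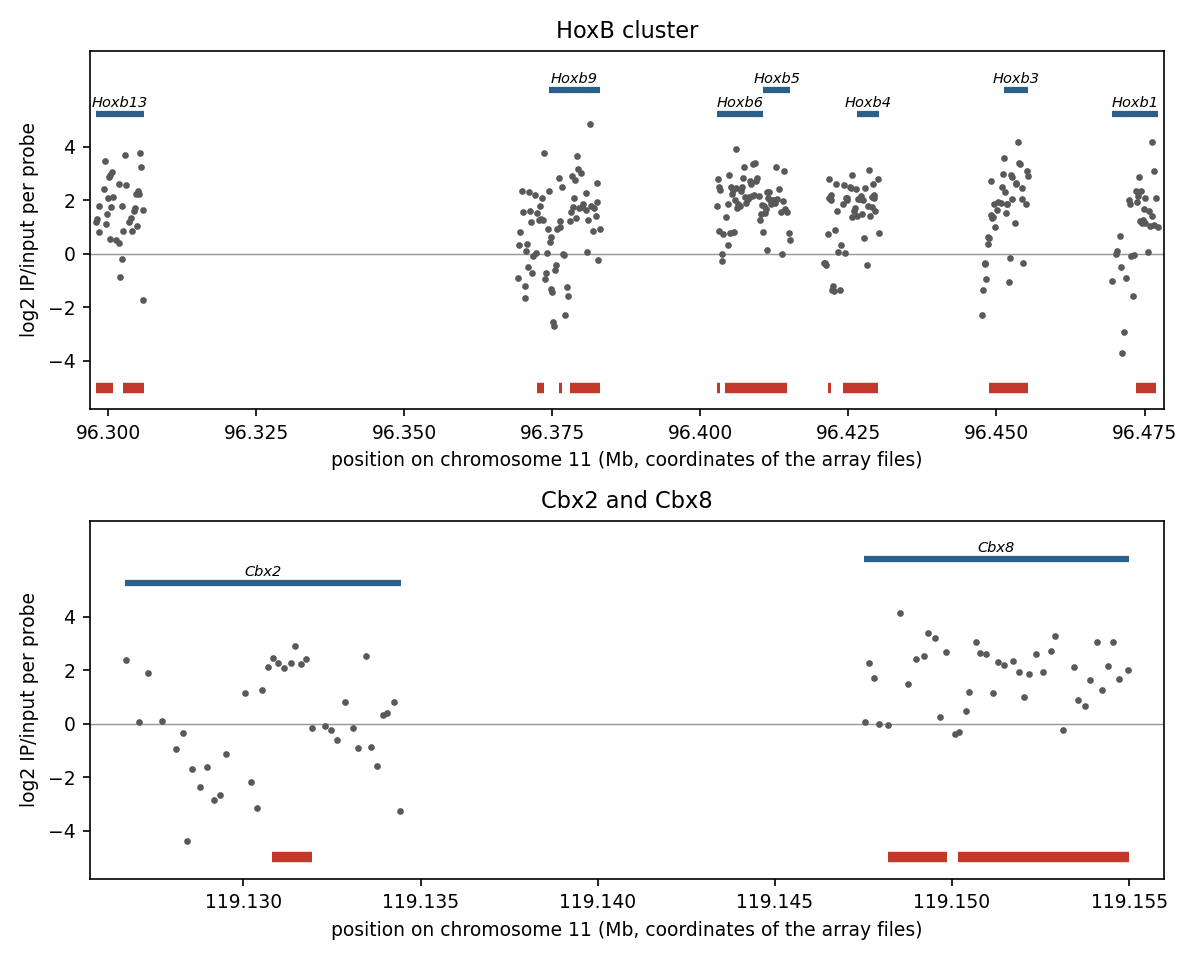
Log2 ratio of each probe (points) against position on chromosome 11, with the tiled genes (blue bars) and the regions with a running mean of at least 1 (red bars), for the HoxB cluster and for Cbx2 and Cbx8. The HoxB stretch holds 7 regions of at least 2000 bp and the stretch of Cbx2 and Cbx8 holds 1, at Cbx8.

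Imprinted genes, expressed from the allele of one parent, had a median of 0.01, at percentile 96.4, with 2 of 25 at or above 1. These were Igf2, also in the signalling list, and Rasgrf1 at 1.12. Kcnk9 had 0.81 and Plagl1 had 0.75. A region of at least 2000 bp was found at 6 of the 25 (24.0%), against 3.09% of all genes. The list passed the middle 95% of its random lists in some other settings, at percentile 99.3 without probes dim in input, 99.7 with the median of probes and 98.7 with at least 20 probes. It was lower than in the main setting in others, at 82.65 with loess, 91.6 without centring and 92.9 with GC-corrected ratios. Histone genes had a median of 0.20, at percentile 100, with 6 of 66 at or above 1 and 1 at or below -1. H2bc9 had 1.96 over 3 probes, H3c2 had 1.74 over 5, H3c7 had 1.62 over 6 and H3c8 had 1.49 over 7. H2bc9 and H3c7 are divergent partners that share upstream probes, and the same 917 bp region covers both. These 2 genes are therefore not separate measurements. With at least 20 probes required, 0 of 38 histone genes were at or above 1, and the list lay at percentile 99.8. The clustered protocadherins, cell adhesion proteins of neurons, had a median of 0.27, at percentile 100, with 9 of 53 at or above 1. Pcdhga10 had 1.74, Pcdha2 1.62, Pcdhga9 1.55 and Pcdhga11 1.38. Among the 31 protocadherins with at least 20 probes the list lay at percentile 86.3, and among the 27 measured within 1000 bp of the start at 89.5, both inside the middle 95% of random lists.

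In the main setting, the lists of olfactory receptors, keratins and ribosomal proteins had medians near the median probe. Without probes dim in input their medians were -0.53, -0.37 and -0.20, where the median of all genes was -0.28. With normexp the olfactory receptors had a median of -0.33. The 862 olfactory receptors had a median of -0.11, at percentile 0, with 1 gene at or above 1 and 13 at or below -1. Their largest values were Olfr538 at -2.17, Olfr462 at -1.71, Olfr374 at -1.68 and Olfr3 at -1.68. Keratin genes had a median of -0.17, at percentile 2.52, with 3 of 71 at or below -1: Krt73 at -1.15, Krt75 at -1.08 and Krt17 at -1.03, followed by Krt13 at -0.82. That percentile lay at the edge of the middle 95%, with 2.38 in another draw of random lists, 0.09 with loess and 47.2 with the median of probes. Ribosomal protein genes had a median of -0.06, at percentile 97.7, and none passed 1 in size. The list fell inside the middle 95% with GC-corrected ratios (96.9), with at least 20 probes (92.1) and within 1000 bp of the start (58.5). It also did so with the best run of 3 probes (48.3), without probes at floor values in both channels (97.3) and with at least 1 probe (96.99). Their largest values were Rpl11 at -0.88, Rpl10a at -0.79, Rpl35a at 0.71 and Rpl22 at -0.70.

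Over all 16882 genes, 337 were at or above 1 and 315 at or below -1. The 5 lowest were Bglap1 at -2.31, Cdk7 at -2.20, Olfr538 at -2.17, Apol9b at -2.15 and Arap1 at -2.12, all on 6 probes or fewer. Among 13713 genes with at least 20 probes, 292 were at or above 1 and 158 at or below -1, and among 7552 with at least 30, 247 were at or above 1 and 50 at or below -1. Of the 337 high genes, 149 (44.2%) were in the 4 developmental lists, which held 1.67% of all genes. Of genes past 1 in size, 51.7% were above; this share was 87.6% with normexp background correction, 89.3% with the deposited series table, 77.7% without centring (484 genes at or above 1) and 63.2% with GC-corrected ratios. It was 64.9% for genes with at least 20 probes, 39.2% without probes at floor values in both channels and 23.6% without probes dim in input.

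Runs of probes with a running mean of at least 1 over at least 2000 bp numbered 518, against 172 with the sign turned. With probes within 1000 bp averaged in place of 500 bp, the counts were 658 and 493. At 4000 bp the counts were 121 and 2, and at 6000 bp 26 and 0. Of the 518, 199 lay at a gene of the developmental lists, and 175 of the 282 listed genes (62.1%) had such a region, against 522 of all genes (3.09%). The longest covered Hoxb6 and Hoxb5 on chromosome 11 (96404220 to 96414625; 10406 bp, 57 probes, mean 2.06). Next came Hoxa10 and Hoxa9 on chromosome 6 (10132 bp, mean 1.64), Lmx1b on chromosome 2 (8097 bp, 1.90), Hoxa11 on chromosome 6 (7967 bp, 2.13) and Lhx9 on chromosome 1 (7920 bp, 1.98). Gata6 carried 7097 bp, Igf2 6693 bp, Gata4 5512 bp, Hoxb1 3473 bp and Cdx2 3346 bp. For Hoxb1 the gene mean was 0.90, below the threshold. Hoxb1 and Cdx2 also had a short region with the sign turned, of 645 bp (mean -1.61) and 658 bp (mean -1.96). The regions with the highest mean were short: Slc22a21 (3.48), Meis2 (3.09, 1368 bp), Meis1 (2.92), Zfp287 (2.88) and Rce1 (2.86). Under 2000 bp, regions with the sign turned outnumbered the others, so the 912 bp region at Pou5f1 (mean 1.58, beside 1650 bp at -1.36), the 473 bp one at Sox2 and the 1152 bp one at Cbx2 were of a size found at least as often below.

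**Figure D3:**
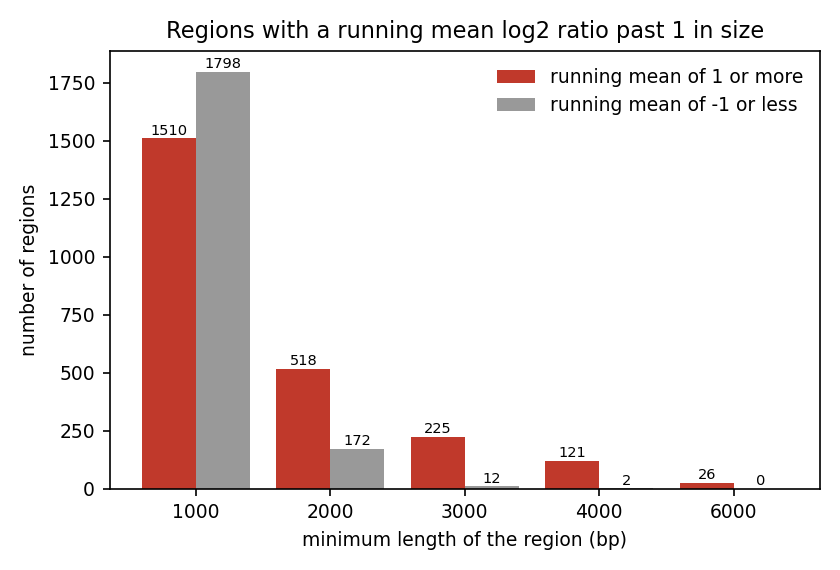
Number of regions (bars) of at least each minimum length in bp, for a running mean of at least 1 (red) and for the sign turned (-1 or less, grey). At 2000 bp there are 518 regions above and 172 below, and at 6000 bp 26 and 0.

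Within high promoters the mean ratio was highest inside the gene. Among genes at or above 1 on slide 1, the mean was 0.54 at positions -5500 to -5000 bp from the transcription start and 1.89 at 500 to 1000 bp inside the gene. On slide 2 the outermost bin had 0.49 and the highest inside bin 1.99. Probes at floor values in both channels went with this profile, at 13.8% of the probes of the outermost bin and 0.510% at 500 to 1000 bp inside, and the bins held different genes (93 and 127 on slide 1). All other genes of slide 1 had -0.25 in the outermost bin and -0.00 at 500 to 1000 bp inside.

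**Figure D4:**
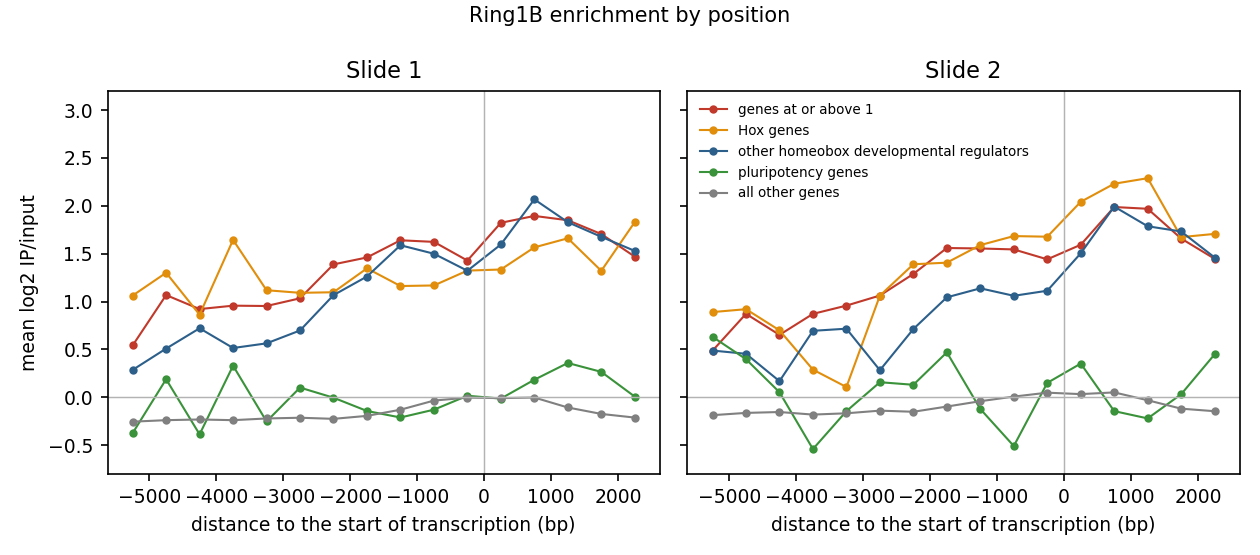
Mean log2 ratio in 500 bp bins of distance to the transcription start, per slide, for genes at or above 1, Hox genes, other homeobox regulators, pluripotency genes and all other genes (points are means over genes). On slide 1 the high genes go from 0.54 at the outermost upstream bin to 1.89 inside the gene.

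On the X chromosome, 8 of 587 genes (1.36%) were at or above 1, against 191 of 7794 autosomal genes (2.45%) of the same slide. The exact binomial 95% intervals overlapped (0.590% to 2.67% and 2.12% to 2.82%; counting error only), and single autosomes of that slide were as low, with 1.11% on chromosome 17 and 1.38% on chromosome 10. No test was made, as genes of one array are not replicates. The left and right parts of one promoter, split at its middle probe, correlated weakly across genes, which are not independent replicates (Pearson 0.20, Spearman 0.14). Where the left part was at or above 1 (551 genes), the right part had a median of 0.37 and lay above 0 in 71.3%. Where the left part was at or below -1 (810 genes), the right part had a median of -0.26 and lay below 0 in 64.9%.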

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

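Among the tests of this part, those on the number of probes per gene and on surrogate signals upstream of the start, and the filters on both and on either channel, were chosen after the result was seen, and the rules for reading the tests on dim probes and on the filter were amended after their values were seen. The design names no second group, so no biological explanation was tested for any pattern.

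The 47 probes of the mitochondrial genome had a median log2 ratio of 0.63 (SD 0.50), and 46 of them lay above 0. They came up because they hold a signal in data that no comparison used. Input signal of these probes had a median of 4641 and immunoprecipitated DNA one of 8192. Brightness was argued against, since the median lay at percentile 100 of random nuclear probe sets matched on it (random median -0.36). Against sets matched on probe GC the median again lay at percentile 100 (random median 0.01). The medians of those sets had bounds of only -0.03 and 0.11, against -0.63 and -0.03 for sets matched on brightness. No set was matched on both, so the GC test cannot tell what GC does at probes this bright. Probe GC therefore stays open. Whether mitochondrial DNA was carried along in the immunoprecipitation also stays open and was not tested.

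Nearly as many genes lay at or below -1 (315) as at or above 1 (337). Dim probes stay open: among genes with at least 20 probes the share at or below -1 was 2.62% in the brightest of 5 equal classes and 0.182% in the dimmest, but floor values hold dim genes near 0, and the dimmest class had 0 genes at or above 1 against 8.86% in the brightest. Few probes per gene may account for part of it, with 0.662% at or below -1 among genes with 30 or more probes against 12.1% among those with 3 to 9. Of the genes with 3 to 9 probes only 3.66% were at or above 1. A spread equal on both sides therefore does not give the whole of the 12.1%. The test of the filter on dim probes decides nothing for these counts, which used no such filter. Where one was used, the share above among genes past 1 in size went with the channel. It was 23.6% for input, 32.3% for both channels, 39.1% for either and 50.1% for immunoprecipitated DNA. In that order, genes at or above 1 numbered 386, 450, 432 and 517. Those at or below -1 numbered 1247, 943, 673 and 514. A filter on a single channel selects on the ratio itself, so these shares describe the filters.

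Among genes at or above 1, the bin within 500 bp upstream of the transcription start was lower than its neighbours by a mean difference of -0.18 (95% bootstrap interval over genes -0.30 to -0.06). Slide 1 had -0.30, whereas slide 2 had -0.09 with an interval that included 0. Probe GC was argued against, since the difference was -0.19 with GC-corrected ratios. Surrogate signals were argued against too, since probes at surrogate values in both channels, 0.886% of those in that bin, moved its mean by only -0.0128. A nucleosome-poor stretch at the start is one untested hypothesis that stays open.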

How the results depend on the processing

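Of the tests here, the minimum of 20 probes, leaving out probes at surrogate values in both channels, and random lists matched on probe number too were chosen after the result was seen. The developmental lists stayed at percentile 100 in every setting, with medians above their random lists of 1.63 to 2.00 for Hox genes, 1.40 to 1.63 for other homeobox regulators, 1.25 to 1.495 for other transcription factors and 0.54 to 1.11 for signalling genes. A count was taken as kept within 1.5 times the main count, and another value within the 95% interval of the main one (bootstrap over genes for lists, SE over probes for genes), which for small list values is wide. Reversed means a turned sign of a gene past 1 in size or of a list outside the middle 95%. By these rules 219 values that answer a comparison were kept, 59 moved and 2 reversed, and for the 71 named genes 769 were kept, 109 moved and 6 reversed. A changed minimum number of probes leaves the mean of a named gene that still qualifies as it was. Those settings therefore count as kept by construction for named genes and say nothing about their stability. Most lists also kept nearly the same members with a minimum of 1 or 6 probes (33 Hox genes in each). A shift of a whole slide largely cancels in list values, as random lists were matched on slide. Kept list values in such settings therefore say little about stability. The median of all genes shifted by 0.11 with normexp, 0.15 without centring, 0.11 with the series table and -0.18 without dim probes. It shifted by 0.13 within 1000 bp of the start and by 1.46 with the best 3 probes. Without centring, values at spots with surrogates in both channels changed too, so its counts are not the effect of centring alone. Signal over background is one limit: 18.2% of the probes of slide 1 and 15.5% of those of slide 2 were at floor values in both channels. List values that follow are medians minus the median of matched random lists. The cause of the moves was not tested, except where the setting itself sets the count (threshold, window, gap, run length, best probes).

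Genes at or below -1, 315 in the main setting, numbered 63 with normexp, 52 with the series table, 139 without centring, 1247 without dim probes, 669 without surrogate probes and 158 with at least 20 probes. The filter on dim probes used the input channel alone and so selects on the ratio itself. At a threshold of 0.5 there were 1288 genes above and 2609 below, and at 1.5 there were 110 and 41. Within 1000 bp of the start there were 1272 and 1038. The highest run of 3 probes was at or above 1 in 11960 genes, and the lowest run was at or below -1 in 13580.

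Developmental transcription factors, at 1.31 in the main setting, had 1.45 with the best 3 probes, 1.495 without dim probes, 1.44 with loess and 1.45 without surrogate probes. Signalling genes (0.68) had 1.08 with the best 3 probes, 0.54 with the median of probes and 1.11 within 1000 bp. Pluripotency genes (0.07) had 0.29 with the best 3 probes and -0.15 within 1000 bp, and fibroblast genes (0.04) had 0.41 with the best 3, -0.0230 with the median of probes and -0.0674 within 1000 bp; neither list was outside the middle 95% in the main setting, so their turned signs are not among the reversed. Olfactory receptors (-0.08) had -0.43 with the best 3 probes, -0.19 without dim probes, -0.0487 with loess, -0.0105 with the median of probes, -0.10 without centring, -0.18 with normexp, -0.20 without surrogate probes and -0.16 with the series table. Keratins (-0.10) had -0.22 within 1000 bp and 0.0245 with the best 3. The turned sign counted as reversed only because keratins lay at percentile 2.38 in the draw of random lists used here. In the draw given above they lay at 2.52, inside the middle 95%. Ribosomal proteins (0.11) reversed to -0.0035 with the best 3. Histone genes (0.27) had 0.0780 with the median of probes and 0.37 within 1000 bp. Protocadherins (0.37) had 0.0751 with the median of probes and 0.0823 with at least 20 probes. Named genes that reversed were Olfr462 (0.0418 within 1000 bp, 0.65 with the best 3), Olfr374 (0.71), Krt73 (2.46), Krt75 (1.00) and Krt17 (0.49), the last 4 with the best 3 probes, a setting that picks the highest run.

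Regions, 5826 above and 10086 below, with 518 and 172 of at least 2000 bp, numbered 14765 and 18884 at a threshold of 0.5 (1272 and 1089 long) and 2104 and 4318 at 1.5 (196 and 20 long). With at least 5 passing probes there were 2768 and 4327, and with a window of 1000 bp 2894 and 6238. Normexp gave 5361 below. Long regions below numbered 278 without dim probes, 306 with a gap of 2000 bp, 87 with one of 500 bp, 81 without centring, 24 with normexp, 493 with a window of 1000 bp (against 658 above) and 50 with one of 300 bp (355 above). The share of autosomal genes at or above 1 was 2.83% without dim probes and 2.98% with normexp.

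No paired analysis was possible because each array was its own slide and no replicate numbers were shared. Not run for want of replicates were leaving out each array, the trend, robust and treat forms of the limma test, camera and fry, differences and agreement between arrays. Fisher's exact test of the X chromosome was not run, as no gene had a test.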

Other observations

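The gene families in this part, and all tests on them, were chosen after the result was seen; they are values without a comparison to random lists. Non-clustered protocadherins, adhesion proteins of the developing nervous system, had a median of 1.30, with 5 of 8 genes at or above 1. Pcdh7 had 1.91, Pcdh8 1.68, Pcdh17 1.59, Pcdh1 1.34 and Pcdh10 1.25. In the DMRT family, known for roles in sex determination and neural development, 3 of 7 genes were at or above 1: Dmrt3 at 1.77, Dmrt2 at 1.45 and Dmrta2 at 1.39. Of 7 Sp factors, Sp8 had 1.76 and Sp9 1.23, both limb and forebrain regulators, whereas Sp1 and Sp3 had 0.12 and 0.23. The rest were below 0, with Sp7 at -0.15, Sp4 at -0.31 and Sp6 at -0.44. Frizzled receptors, which bind Wnt ligands, had a median of 0.65, with Fzd8 at 1.67 and Fzd3 at 1.06. Krueppel-like factors had a median of -0.04, with 0 of 16 at or above 1, and the 230 zinc finger genes named Zfp had a median of -0.13, with only Zfp503 (1.90) at or above 1. At or above 1 were 0 of 21 ephrins and Eph receptors (median 0.03), 1 of 15 semaphorins (0.13), 1 of 15 voltage-gated potassium channels (0.21) and 1 of 19 glutamate receptors (0.26), beside 2.00% of all genes. Kallikreins had a median of -0.49 over 25 genes, and vomeronasal receptors one of -0.09 over 111.

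Promoters of microRNAs had a median of -0.11 over 219 measured, with 9 at or above 1 and 11 at or below -1. The highest, mir-196b at 1.83 (5 probes) and mir-196a-2 at 1.62 (9 probes), lie in Hox clusters. The 10132 bp region at Hoxa10 and Hoxa9 also covers mir-196b. Next were the neural microRNAs Mir9-3 at 1.42 and mir-124a-1 at 1.25, then Mir351 on the X chromosome at 1.19. Mir10a, also in a Hox cluster, had 1.16, followed by mir-129-2 at 1.12, Mir132 at 1.08 and Mir212 at 1.07. Outside every list, 137 genes with at least 20 probes were at or above 1. Among them were Ccnd2, a D-type cyclin, at 1.88, Lmx1b at 1.87, Sim2 at 1.83 and Lmx1a at 1.69.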
